A study of Homo sapiens with 4 samples.

How the data were processed

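RNA was taken from 3 kinds of EPCaT on day 15 and from both cell lines grown together in 2D, with 1 library for each of the 4 groups. Per the labels, RNA for each EPCaT library came from more than 2 tissues and was purified on spin columns, and libraries were made from poly-A RNA with an unstranded TruSeq kit. The authors deposited 1 table of expected counts, which are estimated read counts per gene, made from reads aligned to hg38 and not scaled between libraries. The authors name FastQC, STAR and Partek as the tools behind it. Versions, the gene annotation and the method of counting are not stated. The table lists 17791 gene symbols with their chromosomes, and every column matched a sample. Between 18.2% and 19.9% of the values in a library were not whole numbers, at a tolerance of 0.01, so values were rounded before use.

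Depth was 15687894 counts in the PF EPCaT, 15333450 in PF+2%PEGDA, 13760301 in PF+3%PEGDA and 15641804 in 2D. The 20 most abundant genes took 5.82% to 8.15% of counts. Libraries were scaled with the trimmed mean of M-values in edgeR 4.0.16 (R 4.3.3), and levels are CPM, read counts per 1000000 of the scaled library size. Genes with at least 1 CPM in 1 or more libraries were tested, which left 14851, and 303 genes had no counts anywhere. The other steps ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

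For each pair of libraries the log2 ratio of a gene was computed with a prior count of 0.5, with an exact Clopper-Pearson 95% interval of the ratio. With 1 library per group no test between groups was possible, so the interval covers counting error only. A gene was called higher or lower when its log2 ratio was at least 1 in size and the interval excluded 0. Genes were called in order with PEGDA when PF+3%PEGDA against PF passed this rule and both steps went the same way, each with an interval that excluded 0. Where a library had 0 counts, the fold is a lower bound against a floor of 3 counts in that library. These choices, the gene lists and the rule for named genes were fixed before the data were examined.

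Named genes were taken among those with at least 5 CPM in the higher library, ranked by the bound of the interval nearest to 0. The rule took the 12 highest and 12 lowest over the 3 EPCaTs against 2D, 10 and 10 for PF+3%PEGDA against PF, and 5 and 5 for each other pair of EPCaTs and for the ordered genes. It also took up to 4 members of each list described, and genes fixed in advance, among them CTNNA1 (deleted in PC-3), VIM, CDH1, MKI67, VEGFA, CA9, CCN2, COL1A1, MMP1, CD44 and KRT18. Genes named outside this rule are given as chosen after their values were seen. Symbols were matched to GENCODE release 29, where 17074 of 17791 were found on the same chromosome. Coordinates come from there, on GRCh38. From the same annotation, the share of each gene's 50-mers that occur in another gene was computed. It was 50% or more for 724 of 14455 tested genes that had a value.

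Gene lists held markers of fibroblasts, of epithelium and of endothelial and blood cells; mesenchymal transition, hypoxia, glycolysis, oxidative phosphorylation, S phase, G2 and M phase, cholesterol synthesis, and fatty acid synthesis and lipid storage; the unfolded protein and integrated stress response, heat shock, YAP and TAZ targets, contractile and SRF targets, focal adhesion and integrins, collagens, basement membrane and matrix glycoproteins, matrix crosslinking, and matrix proteases and inhibitors. The others held inflammatory and NF-kB targets, interferon-stimulated genes, antigen presentation, p53 targets, immediate early genes, metallothioneins, antioxidant NRF2 targets, androgen signalling and prostate luminal genes, neuroendocrine genes, stem cell associated genes, mechanosensitive channels and lamins, Wnt, Notch and TGF-beta targets, ribosomal proteins, mitochondrially encoded genes, replication-dependent histones and reference genes. For each list the median log2 ratio over measured members was set beside 10000 random lists of equal size, matched on mean expression in 20 bins. With members at 0 counts set to the floor, 1 median between pairs of libraries moved, that of contractile genes in PF+3%PEGDA against PF+2%PEGDA, from -0.145 to -0.10. The percentiles describe these libraries only, since genes are not replicates. Lists share members, such as COL1A2 and COL5A2 among fibroblast markers and collagens.

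The calls were tested on simulated data that held counting error alone, without variation between cultures or libraries. In a simulated pair of libraries, all of 100 genes changed 4-fold and all of 100 changed 8-fold were recovered. The changed genes were drawn from those with a mean of at least 5 CPM, so recovery of less abundant genes was not tested. Among 14651 genes with no simulated difference, 36 to 50 were called in a pair of libraries. The 95% interval held the true ratio for 95.6% of these genes. Alternatives were DESeq2 1.42.0 size factors, total counts as the only scaling, no filter or a filter at 5 CPM, a prior count of 5, a 4-fold rule, library sizes without the most abundant genes, and each EPCaT left out in turn. Added after seeing the data were library sizes without ribosomal RNA, genes with under 50% of shared 50-mers, and removal of a trend with transcript length and GC content. Genes on the Y chromosome were left out of the values by gene.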

Results

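Gene expression was measured by RNA sequencing in engineered prostate cancer tissues (EPCaTs) and in a flat coculture of the same cells. An EPCaT holds PC-3 cells, a line from a prostate cancer metastasis, and BJ-5ta fibroblasts, foreskin fibroblasts immortalised with telomerase, in a hydrogel of polyethylene glycol and fibrinogen (PF). The cells were seeded at 5 PC-3 to 1 BJ-5ta, and the tissues were taken on day 15. The PF+2%PEGDA and PF+3%PEGDA gels also held polyethylene glycol diacrylate (PEGDA), a crosslinker, at 2% or 3%. There was 1 library for each of the 4 groups, so no comparison has replicates and no p-value between groups is given. Total counts were 15687894 in the PF EPCaT, 15333450 in the PF+2%PEGDA EPCaT, 13760301 in the PF+3%PEGDA EPCaT and 15641804 in the 2D coculture. A single count was worth 0.05998 to 0.0734 CPM (read counts per 1000000 of the scaled library size). Higher and lower below mean at least 2-fold apart with a 95% interval that excludes equality. These intervals cover counting error only.

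The first comparison set each EPCaT against the 2D coculture, and so asked how expression in the gel differed from that in flat culture. Most genes of the response to low oxygen were higher than 2D in all 3 EPCaTs. Medians of the cell division lists were above 0 in each EPCaT, though with 3% PEGDA most of their members did not pass the size rule. Most fibroblast markers, collagens and genes of the unfolded protein response were lower in all 3. ANGPTL4, a secreted lipase inhibitor induced by hypoxia (chromosome 19, 8363289 to 8374373, GRCh38), measured 403, 692 and 705 CPM in the PF, 2% PEGDA and 3% PEGDA tissues and 5.38 CPM in 2D. COL1A1, which encodes the main collagen chain of fibroblasts (chromosome 17, 50183289 to 50201632), measured 307, 365 and 246 CPM and 1742 CPM in the same order. HSPA5, the chief chaperone of the endoplasmic reticulum (chromosome 9, 125234853 to 125241330), was 4.16- to 5.41-fold lower in the EPCaTs.

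Of 28 hypoxia genes, 20 were higher than 2D in all 3 EPCaTs and 0 lower, with a median log2 ratio of 1.92 for the mean of the 3 EPCaTs. That median lay above all 10000 random lists of equal size and expression. EGLN3, an oxygen-sensing prolyl hydroxylase, was 88.4- to 158-fold higher and HILPDA, which promotes lipid droplets, 10.9- to 18.3-fold. The carbonic anhydrase gene CA9 had 1 count in 2D and 5.64, 8.44 and 9.03 CPM in the 3 EPCaTs, and its ratio in the PF+3%PEGDA EPCaT was 87.6 (interval 23.3 to 5270). VEGFA measured 215, 145, 159.7 and 153 CPM in the PF, 2% PEGDA, 3% PEGDA and 2D libraries, so this angiogenic factor did not pass the size rule. Among 18 glycolysis genes, 10 were higher in all 3 EPCaTs and 0 lower (median 1.48). PGK1, which makes ATP in glycolysis, was 5.45- to 8.54-fold higher, and the aldolase gene ALDOC 7.01- to 14.5-fold. The 25 oxidative phosphorylation genes had a median of -0.12, with 0 higher and 0 lower. ATP5F1B, COX4I1, CYC1 and UQCRC1, the most abundant of them, all lay within 2-fold of 2D.

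The 26 genes of G2 and M phase had medians of 2.12 in the PF EPCaT, 1.44 in the PF+2%PEGDA EPCaT and 0.51 in the PF+3%PEGDA EPCaT. The number higher than 2D was 23, 19 and 7, respectively. MKI67, the gene of the proliferation marker Ki-67 (chromosome 10, 128096659 to 128126385), measured 119, 49.03 and 25.9 CPM in these EPCaTs and 7.56 CPM in 2D. CDK1, the kinase that drives mitosis, was 6.89- to 13.6-fold higher and CCNA2, which encodes cyclin A2, 4.39- to 9.58-fold. Of 25 S phase genes, 9 were higher in all 3 EPCaTs (median 1.14). They included RRM2 and TYMS, enzymes of nucleotide synthesis, at 11- to 20-fold and 6.16- to 8.86-fold, CCNE2 at 6.66- to 24.5-fold and GINS2 at 4.08- to 5.31-fold.

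Genes of the unfolded protein and integrated stress response were lower as a group. Of 20, 13 were lower in all 3 EPCaTs and 0 higher (median -1.66, below all 10000 random lists). CHAC1, a glutathione-degrading enzyme induced by ATF4, was 9.46- to 11.8-fold lower. TRIB3 was 4.02- to 7.54-fold lower and the chaperone gene HSP90B1 3.58- to 3.83-fold. The 12 heat shock genes had a median of -0.04. Among them only BAG3 was lower in all 3 EPCaTs (3.76- to 4.57-fold).

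Fibroblast markers were lower. Of the 24 listed, 21 were measured and 15 were lower in all 3 EPCaTs, with 0 higher (median -1.88). PDGFRB, a growth factor receptor of fibroblasts and pericytes, was 8.91- to 13.8-fold lower, COL1A2 7.16- to 17.5-fold, COL5A1 5.20- to 7.90-fold and COL1A1 4.77- to 7.07-fold. Of 22 collagen genes, 14 were lower in all 3 EPCaTs (median -1.57), among them COL4A1 (5.70- to 6.87-fold), COL5A3 (5.90- to 23.7-fold) and COL11A1 (12.3- to 26.6-fold). COL4A6 of this list was higher, as was COL2A1, a collagen gene outside the list. Among 20 basement membrane and matrix glycoprotein genes, 8 were lower in all 3 and 1 was higher (median -1.03). FN1, the fibronectin gene, measured 311, 414, 339 and 2390 CPM in the PF, 2% PEGDA, 3% PEGDA and 2D libraries. THBS2, TNC and EFEMP1 were 3.89- to 4.83-fold, 3.60- to 5.94-fold and 3.46- to 8.19-fold lower.

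Genes that respond to mechanical contact were among the lower ones. The share of BJ-5ta cells was not separated from expression per cell here, nor for the mesenchymal transition genes. Of 23 YAP and TAZ targets, 9 were lower in all 3 EPCaTs and 0 higher (median -0.84). They included FJX1 (8.30- to 10.6-fold), DLC1 (9.90- to 12.9-fold), the receptor gene AXL (3.77- to 6.09-fold) and CCN1 (3.22- to 4.99-fold). CCN2, the connective tissue growth factor gene, measured 71.7, 108, 78.95 and 179 CPM in the same order and was lower in the PF and PF+3%PEGDA EPCaTs. Of 17 contractile genes and targets of the transcription factor SRF, 6 were lower in all 3 (median -0.97). TAGLN, an actin-binding protein gene of smooth muscle and myofibroblasts, was 12.2- to 12.9-fold lower, TPM1 2.74- to 3.12-fold and ACTA2 4.10- to 12.8-fold. CNN1 had 6, 1 and 0 counts in the EPCaTs and 77 in 2D. The 22 focal adhesion and integrin genes had a median of -0.24, with 5 lower in all 3 and 1 higher. ITGA11, FERMT2 and ITGA3, a laminin receptor subunit, were among the lower ones, with 3144 CPM of ITGA3 in 2D and 661, 719.7 and 689 CPM in the EPCaTs. ITGB6, an epithelial integrin subunit gene, was 3.63- to 3.93-fold higher.

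Of 20 mesenchymal transition genes, 8 were lower in all 3 EPCaTs and 0 higher (median -1.06). SNAI2, a repressor of epithelial genes, was 8.65- to 13.1-fold lower and the N-cadherin gene CDH2 5.26- to 10.2-fold. VIM, the vimentin gene, measured 623, 1135 and 1394 CPM in the 3 EPCaTs and 1851 CPM in 2D. It was lower in the PF EPCaT alone. Of 28 epithelial markers, 5 were higher in all 3 EPCaTs and 1 was lower (median 0.38). CDH1, the E-cadherin gene, was 2.19- to 2.45-fold higher, OVOL1 3.43- to 4.18-fold, ELF3 2.55- to 2.67-fold and ST14 2.45- to 3.20-fold. LCN2 was 4.31- to 5.08-fold lower, and KRT18 lay within 2-fold (539.7, 635, 604 and 646 CPM). Of 13 androgen signalling and prostate luminal genes, 5 were higher in all 3 EPCaTs and 1 was lower (median 1.08). TMPRSS2, a serine protease gene of the prostate, was 7.08- to 9.02-fold higher, SLC45A3 5.67- to 7.11-fold, the prostatic acid phosphatase gene ACP3 18.9- to 23-fold and NDRG1 8.74- to 11.1-fold. NDRG1 is also a member of the hypoxia list.

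Genes that cut or crosslink matrix went both ways. Of 26 matrix proteases and inhibitors, 5 were lower in all 3 EPCaTs and 1 was higher (median -0.63). The higher one was MMP10, a stromelysin gene (12.1- to 19.5-fold), and CTSL and PLAT were among the lower ones. MMP1, the interstitial collagenase gene, measured 58.96, 64.1, 77.99 and 47.9 CPM in the PF, 2% PEGDA, 3% PEGDA and 2D libraries. Of 14 matrix crosslinking genes, P4HA1, a collagen prolyl hydroxylase gene, was 3.05- to 4.23-fold higher (median of the list -0.27). TGM2 and SERPINH1 were 3.24- to 4.57-fold and 2.30- to 3.28-fold lower.

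Among the 12 genes ranked highest against 2D, HSD17B13, a lipid droplet enzyme gene, measured 102, 168 and 185 CPM in the EPCaTs and 0.273 CPM in 2D. FABP4, a fatty acid carrier gene, was 38.3- to 79.1-fold higher. FPR3, a formyl peptide receptor gene (chromosome 19, 51795163 to 51826189), had 0 counts in 2D and was at least 289- to 351-fold higher against a floor of 3 counts. FAM177B, also at 0 counts in 2D, was at least 64.9- to 68.7-fold higher. ABCB11, the bile salt export pump gene, and PPFIA4 had 1 count each in 2D. In the PF EPCaT their ratios were 175 (interval 45.8 to 10200) and 358 (interval 94 to 20800). MUC16, the mucin gene behind the CA-125 antigen, was 89.8- to 202-fold higher and C2orf72 58.7- to 124-fold. COL2A1, a cartilage collagen gene (chromosome 12, 47972965 to 48004554), was 27.7- to 36.5-fold higher, and SCNN1G, an epithelial sodium channel subunit gene, 31.4- to 32.5-fold. ANGPTL4 and EGLN3 completed the set.

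Among the 12 ranked lowest, SULF1, which trims heparan sulfate, measured 6.72, 4.38 and 2.35 CPM in the EPCaTs and 149.5 CPM in 2D. BGN, the biglycan gene, was 9.59- to 10.8-fold lower, MGP 13- to 19.9-fold and IGFBP7 8.99- to 17.5-fold. ESM1, which encodes endocan, was 17.9- to 29.4-fold lower, and the adrenergic receptor gene ADRA1D 17.6- to 23-fold. The cytokine gene IL24 measured 20.6 CPM in 2D and 0.780, 0.129 and 1.03 CPM in the EPCaTs. IGF2BP1, an RNA-binding protein gene, measured 10.2 CPM in 2D and 0.540, 0.0644 and 0.514 CPM in the EPCaTs. SLAMF7 was 13.5- to 18-fold lower, and TAGLN, CHAC1 and PDGFRB were the others.

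**Figure D1:**
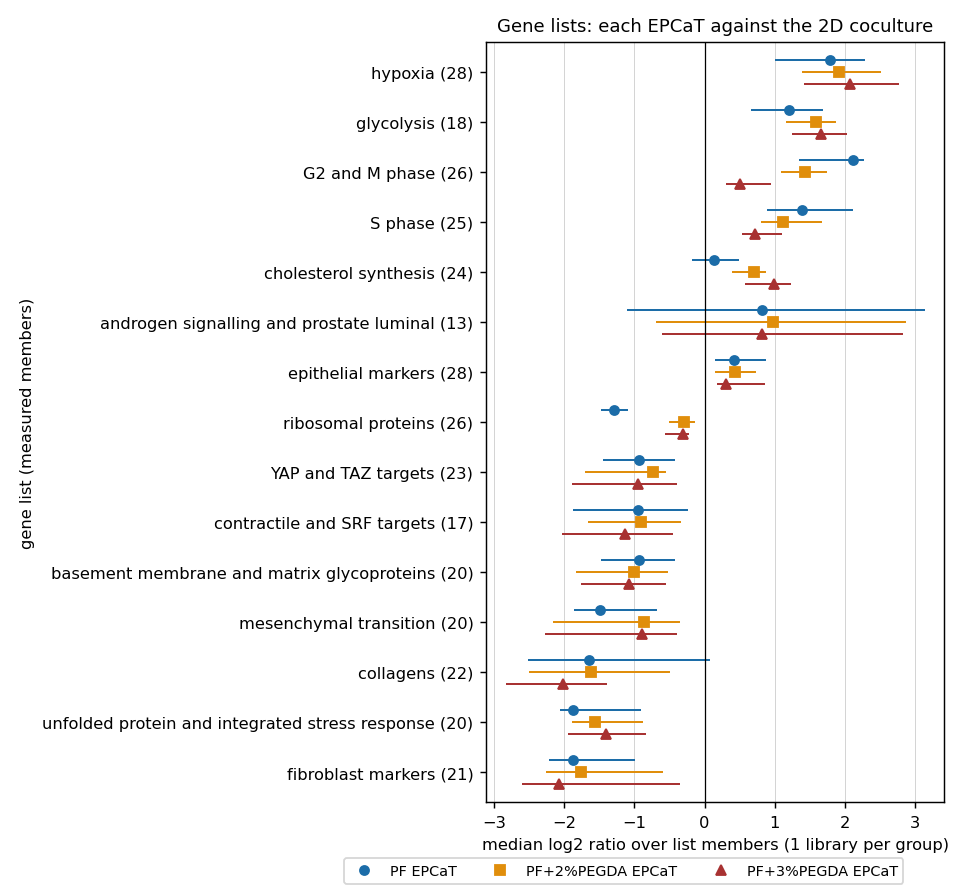
Median log2 ratio of 15 gene lists in each EPCaT against the 2D coculture, with 1 library per group; points are medians over the measured members given in brackets, and lines are 95% intervals of the median over members, not over replicates. Hypoxia and glycolysis lie to the right in all 3 EPCaTs and fibroblast markers to the left, and the G2 and M phase medians run from 2.12 to 0.51.

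Across all 14851 tested genes, 2449 were higher and 1785 lower in the PF EPCaT than in 2D. The PF+2%PEGDA EPCaT had 1843 higher and 1403 lower, and the PF+3%PEGDA EPCaT 1791 and 1540. In all 3 EPCaTs, 1164 genes were higher and 902 lower, where lists of these sizes drawn independently would share 36.7 and 17.5. The 3 ratios share the 2D library, and part of these counts may come from that library. With counting error alone simulated, and no variation between cultures or libraries, 3 genes were called in all 3, which is no measure of what unchanged cultures would give. At the 4-fold rule the counts in all 3 EPCaTs were 451 higher and 216 lower. With total counts as the only scaling, 3007 genes were higher and 1386 lower in the PF EPCaT. The labels give neither the day nor the cell ratio of the 2D coculture, so the gel and these conditions are not separated.

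The share of each cell line was examined next through CTNNA1, the alpha-catenin gene (chromosome 5, 138610967 to 138935034), in which PC-3 carries a homozygous deletion. CTNNA1 measured 5.40, 6.19 and 8.29 CPM in the PF, 2% PEGDA and 3% PEGDA tissues and 33.1 CPM in 2D, which was 3.98- to 6.10-fold lower. Its mean log2 ratio to 2D over the 3 EPCaTs was -2.34. Reads from a part of the gene that PC-3 retains would also be counted, and 1 gene does not separate the share of a cell line from its expression per cell. Of 7 measured endothelial and blood cell markers, cell types not seeded here, 4 were higher in all 3 EPCaTs (median 2.12). These were PECAM1 (9.11- to 12-fold), KDR (6.98- to 10.3-fold), ESAM (4.07- to 4.88-fold) and LYZ (5.17- to 7.20-fold). Log2 ratios of the 7 ran from -1.68 to 3.19 in PF, -1.10 to 3.52 with 2% PEGDA and -0.83 to 3.59 with 3% PEGDA. Not every marker was therefore above 2D. Of the 14 genes listed, the others were not measured, being absent from the table or under 1 CPM in every library.

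**Figure D2:**
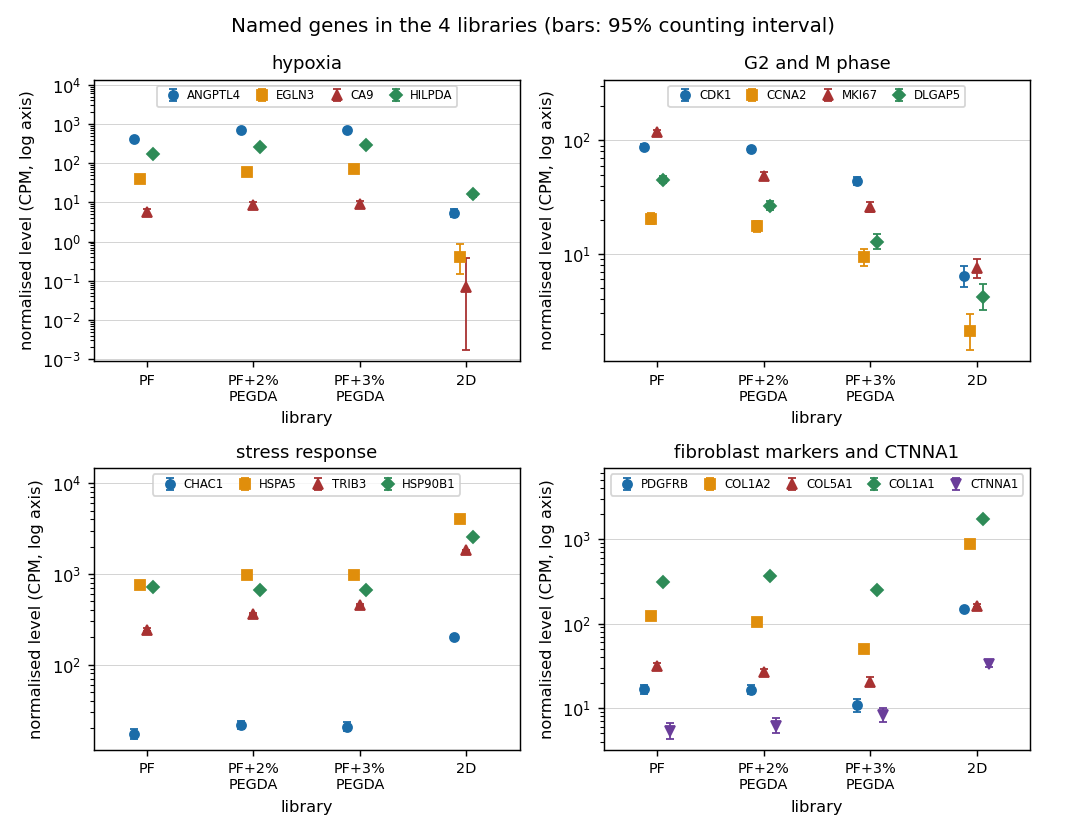
Normalised level in CPM, on a log axis, of named genes in the 4 libraries, with bars for the 95% counting interval. Hypoxia genes are high in every EPCaT, MKI67 runs from 119 to 25.9 CPM across the EPCaTs, and CTNNA1 is highest in 2D.

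The second comparison set the PF+3%PEGDA EPCaT against the PF EPCaT, the ends of the series by which the study varied tumour tissue stiffness. Many genes of mitosis and some of DNA replication were lower with 3% PEGDA, as were several collagens. Some genes of cholesterol synthesis, metallothioneins and ribosomal proteins were higher. MKI67 measured 119 CPM in PF and 25.9 CPM with 3% PEGDA, 4.60-fold lower. MSMO1, a sterol oxidase gene, went from 81.2 to 225 CPM, 2.77-fold higher.

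Of 26 G2 and M phase genes, 19 were lower with 3% PEGDA and 0 higher, and of 25 S phase genes 6 were lower. The medians were -1.15 and -0.72, both below all 10000 random lists. CENPE and CENPF, kinetochore genes, were 5.45-fold and 4.74-fold lower, and DLGAP5, a spindle gene, 3.52-fold. MCM10 and CDT1, which act in replication licensing and initiation, were 3.61-fold and 2.29-fold lower, CCNE2 3.65-fold and UHRF1 2.62-fold. Epithelial markers had a median of -0.06 with none past the size rule. KRT19, KRT8, KRT7, CLDN4 and CDH1 all lay within 2-fold. Of 14 genes of mechanosensitive channels and the nuclear lamina, SYNE2 (2.70-fold) and LMNB2 (2.15-fold) were lower and the channel gene TRPV4 2.10-fold higher (median -0.36). Against 2D, SYNE2 and LMNB1 of this list were higher in all 3 EPCaTs (median 0.19).

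Of 22 collagen genes, 9 were lower with 3% PEGDA and 0 higher (median -0.71). COL7A1 was 4.41-fold lower, COL4A6 4.20-fold, COL5A2 2.89-fold and COL1A2 2.45-fold. Fibroblast markers had a median of -0.32, and the 2 that were lower were COL5A2 and COL1A2. CTNNA1 was 1.53-fold higher (interval 1.15 to 2.05), under the size rule. LAMA5, a laminin chain gene, was 2.30-fold lower, EFEMP1 2.37-fold and LAMA1 3.59-fold (median of the basement membrane list -0.09, which turned to 0.17 with the trend with transcript length and GC removed). LOX, a collagen crosslinking enzyme gene, went from 26.2 to 69.2 CPM and LOXL3 was 2.41-fold lower. Of 26 matrix proteases and inhibitors, only the stromelysin gene MMP3 passed the rule (2.98-fold higher), with a list median of 0.52. VIM was 2.24-fold higher, while the mesenchymal transition list had a median of 0.42, 2 higher and 1 lower. YAP and TAZ targets had a median of -0.09, with FOXF2 the only one past the rule (2.91-fold lower), and CCN2 measured 71.7 and 78.95 CPM. Among contractile genes (median -0.18, and -0.078 with that trend removed), TPM2 was 4.40-fold lower and ACTA2 2.07-fold.

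Of 24 cholesterol synthesis genes, 4 were higher and 0 lower with 3% PEGDA (median 0.76, above all 10000 random lists). Beside MSMO1 these included INSIG1 (2.52-fold) and CYP51A1 (2.23-fold), the last with 79.6% of its 50-mers in other genes. Against 2D, HMGCS1 of this list was 2.04- to 3.42-fold higher in all 3 EPCaTs (median 0.65). SCD, a fatty acid desaturase gene, was 2.07-fold higher with 3% PEGDA, and the lipid droplet gene PLIN2 2.31- to 3.79-fold higher than 2D (list medians 0.39 and 0.20). Hypoxia genes had a median of 0.45, glycolysis genes 0.41 and oxidative phosphorylation genes 0.34, each with 1 member past the size rule: LOX, ALDOC and NDUFA4. With the trend with transcript length and GC removed, the oxidative phosphorylation median was 0.035. Of the 7 metallothioneins, 4 were measured and 3 were higher with 3% PEGDA. MT1X was 5.44-fold higher, MT2A 3.79-fold and MT1F 2.15-fold. Against 2D, MT2A, MT1F and MT1M were lower in all 3 EPCaTs (list median -1.99). Of 17 antioxidant targets of NRF2, the heme oxygenase gene HMOX1 was 2.93-fold higher, FTL 2.71-fold and AKR1C3 2.57-fold (median 0.34).

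The PF library stood apart from the other EPCaTs in several measures. Of 26 ribosomal protein genes, 10 were higher with 3% PEGDA than in PF and 11 with 2% PEGDA (medians 0.87 and 0.94). RPS14 was 2.73-fold higher with 3% PEGDA, RPL23 2.51-fold, RPL27 2.44-fold and RPS19 2.40-fold. Against 2D, 19 of these genes were lower in PF, 0 with 2% PEGDA and 0 with 3% (medians -1.30, -0.30 and -0.31). The nuclear RNAs NEAT1 (chromosome 11, 65422774 to 65445540) and MALAT1 (chromosome 11, 65497688 to 65506516), chosen after their values were seen, measured 1565, 267, 252 and 196 CPM and 369, 47.4, 82.4 and 15.5 CPM in the PF, 2% PEGDA, 3% PEGDA and 2D libraries. Genes for ribosomal RNA took 2.16% of counts in PF, 0.685% with 2% PEGDA, 0.717% with 3% PEGDA and 1.597% in 2D. In 3% PEGDA against PF, the 10% of genes with the shortest transcripts had a median log2 ratio of 0.29 and the 10% with the longest -0.18. These values accompany every comparison with PF, that of the cell division genes included.

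By the ranking rule, the genes highest with 3% PEGDA were led by small or repeated loci. UTS2, the urotensin 2 gene, was 15.4-fold higher, RPL36A 7.04-fold, RPL39 6.15-fold and RPS27 4.78-fold. MTRNR2L2 and MTRNR2L8, nuclear copies of mitochondrial sequence, were 6.99-fold and 8.06-fold higher. MT1X, PGBD3 (4 counts in PF and 110 with 3% PEGDA), CERS6-AS1 (4 and 370 counts) and SFT2D3 were the others. SFT2D3 had 0 counts in PF and was at least 52.6-fold higher, with 100% of its 50-mers in other genes. The lowest were mostly read-through or pseudogene loci. CHKB-CPT1B and MSH5-SAPCD1 had 0 counts with 3% PEGDA and were at least 46.3-fold and 24-fold lower. PVRIG2P had 221 counts in PF and 2 with 3% PEGDA, and MST1 103 and 1. FER1L4 was 10-fold lower, the heat shock factor gene HSF4 11.1-fold, BCL2L2-PABPN1 9.94-fold, ABCF2-H2BE1 10.9-fold, STAG3L5P-PVRIG2P-PILRB 9.59-fold and GOLGA8B 7.16-fold. Of their 50-mers, CHKB-CPT1B shares 91.2% with other genes, MSH5-SAPCD1 95.2%, BCL2L2-PABPN1 96.7%, PVRIG2P 100%, STAG3L5P-PVRIG2P-PILRB 91.4%, CERS6-AS1 65.2% and GOLGA8B 67.048%. ABCF2-H2BE1 and PGBD3 had no such value. How the authors assigned shared reads is not stated, and no test here assigned them another way. TUBA1A, an alpha-tubulin gene named after its values were seen, measured 57.3, 182, 269 and 63.1 CPM in the PF, 2% PEGDA, 3% PEGDA and 2D libraries.

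**Figure D3:**
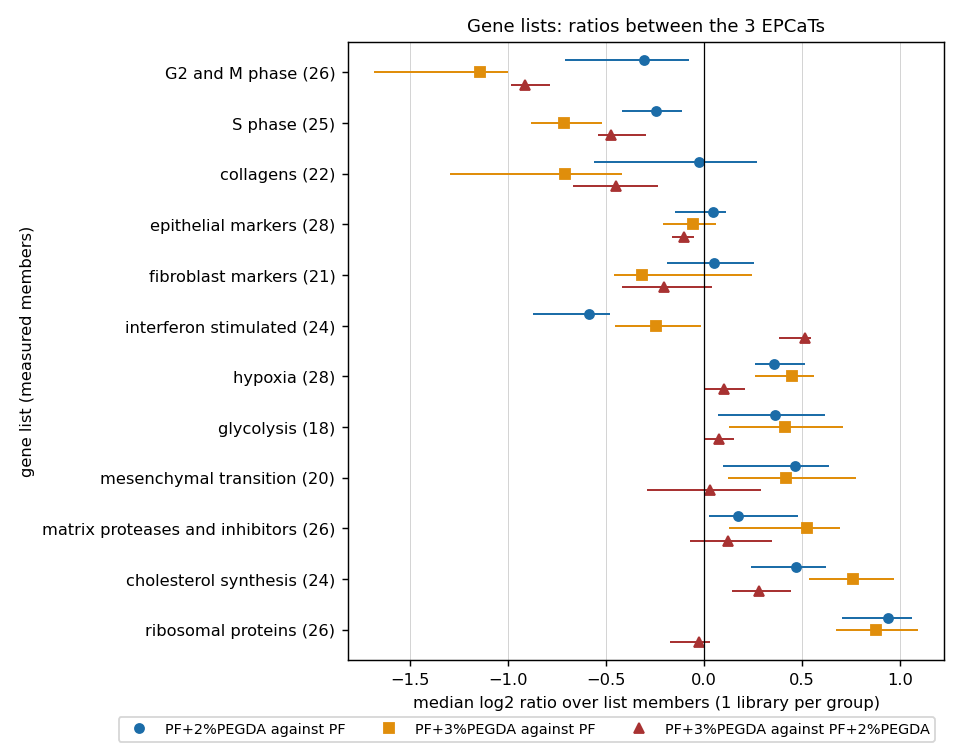
Median log2 ratio of 12 gene lists between the 3 EPCaTs, with 1 library per group; points are medians over the measured members in brackets and lines 95% intervals of the median over members, not over replicates. G2 and M phase medians are -0.31 for PF+2%PEGDA against PF and -0.92 for PF+3%PEGDA against PF+2%PEGDA, and ribosomal proteins differ from PF in both PEGDA EPCaTs.

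In total, 539 genes were higher and 1115 lower with 3% PEGDA than in PF. Among genes with at least 5 CPM in 1 or more libraries these counts were 274 and 686, and at the 4-fold rule they were 99 and 293.

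The third comparison set the PF+2%PEGDA EPCaT against PF, the lower amount of crosslinker. Some interferon-stimulated genes were lower with 2% PEGDA, and ribosomal protein genes were higher as given above. Of 24 interferon-stimulated genes, 5 were lower and 0 higher (median -0.59, below all 10000 random lists). XAF1, an interferon-induced apoptosis factor gene, went from 28.6 to 5.48 CPM. Of 26 G2 and M phase genes, 3 were lower with 2% PEGDA (median -0.31), MKI67 among them (2.43-fold). Of 25 S phase genes 1 was lower (median -0.25), and of 22 collagens 3 were lower (median -0.03). MT1X was 3.17-fold higher and RPL39 6.65-fold. The other genes ranked highest were CERS6-AS1, PGBD3, UTS2 (11.8-fold) and GPR75-ASB3. MSH5-SAPCD1, with 0 counts at 2% PEGDA, was at least 27.3-fold lower, and PLA2G4B, C8orf44-SGK3, BOLA2 and LOC727751 ranked beside it. In all, 442 genes were higher and 825 lower, and 213 and 441 among genes with at least 5 CPM. Genes higher than PF in both PEGDA EPCaTs numbered 250 and lower ones 548, where independent lists would share 16 and 61.9. Both ratios share the PF library, and part of these counts may come from that library. The same simulation of counting error alone called 4 genes in both, again without variation between cultures or libraries.

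The fourth comparison set 3% against 2% PEGDA, which leaves the PF library out. Cell division genes had medians below 0 at the higher amount of PEGDA, and interferon-stimulated genes a median above 0. Of 26 G2 and M phase genes, 7 were lower and 0 higher (median -0.92), and of 25 S phase genes 1 was lower (median -0.48). CDK1 measured 83.4 CPM at 2% and 44.3 CPM at 3%, and DLGAP5 26.7 and 12.8 CPM. KIF20A, a mitotic kinesin gene named after its values were seen, was 3.00-fold lower. Of 22 collagens, 4 were lower (median -0.45), among them COL1A2 (2.12-fold) and COL5A3 (4.02-fold). MMP3 was 2.68-fold higher. Interferon-stimulated genes had a median of 0.51, with 1 past the size rule, and ribosomal protein genes -0.03. By the ranking rule FTH1P3, SFT2D3, LOC727751, BIVM-ERCC5 and CBSL were highest, and DNAAF4-CCPG1, GPR75-ASB3, ABCF2-H2BE1, ERV3-1-ZNF117 and IPO11-LRRC70 lowest. In all, 275 genes were higher and 358 lower. Among genes with at least 5 CPM these counts were 43 and 118, and with no filter on low counts 417 genes were higher.

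The last comparison asked which genes went in order from PF through 2% to 3% PEGDA. Upward in order went 138 genes, and 331 went downward, with each step outside counting error. The downward set held 13 of 26 G2 and M phase genes, 6 of 25 S phase genes and 4 of 22 collagens. The upward set held 4 of 24 cholesterol synthesis genes, 3 of 17 antioxidant NRF2 targets and 2 of 4 metallothioneins. CERS6-AS1, SFT2D3, UTS2, RPL36A and MTRNR2L2 ranked highest upward, and CHKB-CPT1B, PVRIG2P, MST1, FER1L4 and BCL2L2-PABPN1 lowest. FER1L4 measured 150.1, 22.6 and 14.97 CPM in order, and UTS2 1.08, 13.1 and 17.1 CPM. CD44, a hyaluronan receptor gene, measured 169, 243 and 275 CPM and stayed under the size rule. Of 1684 genes past the size rule in 1 or both steps, 349 had steps in opposite directions and 206 in the same direction, each outside counting error. At the 4-fold rule 21 genes went up in order and 72 down, and with total counts as the only scaling 85 went up.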

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

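Removal of the trend with transcript length and GC content, library sizes without ribosomal RNA and the limit of 50% on shared 50-mers were chosen after seeing the data. Of 118 recomputed counts of genes under settings fixed in advance, 94 stayed within 1.5 times the value reported and 24 did not, while all 48 added ones did. Of 896 recomputed list medians under settings fixed in advance, 894 stayed within the interval of the median, as did 438 of the added ones, and 6 added ones did not. The metallothioneins and neuroendocrine genes were too few for an interval, so the range of their members was used. For single genes other than CTNNA1, 3088 recomputed ratios under settings fixed in advance stayed within the counting interval, 198 moved beyond it with the same sign and 4 changed sign; of the added ones 1445 stayed, 162 moved and 4 changed sign.

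The 4-fold rule gave fewer genes by its construction. The counts higher and lower were 960 and 461 in PF against 2D, 662 and 395 in PF+2%PEGDA against 2D, and 675 and 466 in PF+3%PEGDA against 2D. They were 451 and 216 in all 3 EPCaTs, 96 and 208 in PF+2%PEGDA against PF, 99 and 293 in PF+3%PEGDA against PF, and 75 and 98 in PF+3%PEGDA against PF+2%PEGDA. In order with PEGDA 21 genes went up and 72 down. With at least 5 CPM, fewer genes were tested. The counts were 213 and 441 in PF+2%PEGDA against PF, 274 and 686 in PF+3%PEGDA against PF, and 43 and 118 in PF+3%PEGDA against PF+2%PEGDA. There the share of called genes that were higher was 26.7%, 16.7 points below that reported. Without a filter, 417 genes were higher in PF+3%PEGDA than in PF+2%PEGDA. With 1 EPCaT left out, 1308 to 1454 genes were higher and 1043 to 1094 lower in both others than in 2D. By construction these counts could not fall below those for all 3 EPCaTs.

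With total counts as the only scaling the median ratio of all genes shifted by 0.18 in PF against 2D, 0.11 in PF+2%PEGDA against 2D and -0.10 in PF+3%PEGDA against PF, on the log2 scale. Genes going up in order were then 85, and the ribosomal protein median of the EPCaTs against 2D was -0.51. The share of called genes that were higher in PF than in 2D was 68.4%, against 57.8% as reported. The sign turned for CLDN4 (-0.047) and KRT8 (-0.001) in PF+3%PEGDA against PF, COX4I1 (0.017) in PF+2%PEGDA against 2D and UQCRC1 (0.022) in PF against 2D. A prior count of 5 gave the metallothioneins a median of -1.60 against 2D.

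With the length and GC trend removed, oxidative phosphorylation genes had medians of 0.032 for the EPCaTs against 2D and 0.19 in PF+2%PEGDA against PF, and unfolded protein genes 0.15 in the latter. In PF+3%PEGDA against PF, contractile genes had -0.078, oxidative phosphorylation genes 0.035 and basement membrane genes 0.17, a turn of sign, and epithelial markers -0.056 in PF+3%PEGDA against PF+2%PEGDA. The sign turned for ATP5F1B (0.10) and UQCRC1 (0.012) in PF against 2D, KRT18 (0.05) in PF+3%PEGDA against 2D and NOTCH3 (0.19) in PF+3%PEGDA against PF. Beyond the construction of the settings, the cause was not tested. Depth limits genes near the floor of 0.180 to 0.220 CPM that 3 counts allow.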

Other observations

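Some tests below were chosen after the results were seen. They were those on the share of PC-3 cells, on nuclear RNA for the cell division genes and on the share of BJ-5ta cells. Brackets after a list median hold its interval over member genes. Genes are not replicates, so these brackets do not cover variation between cultures or libraries. Brackets after the CTNNA1 ratio hold its counting interval.

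Several groups not yet described also differed between the EPCaTs and the 2D coculture. Of 21 inflammatory and NF-kB targets, 6 were lower in all 3 EPCaTs and 1 was higher (median -0.62). The chemokine genes CXCL1 and CCL2 were 5.69- to 6.23-fold and 5.34- to 7.31-fold lower and IL6 5.36- to 10.7-fold, and PTGS2, a prostaglandin synthase gene, was 2.53- to 5.20-fold higher. With 3% PEGDA against PF, CXCL8 and PTGS2 were 2.69-fold and 2.06-fold higher, CSF2 had 5 counts against 0, and CXCL2 was 3.32-fold lower (list median 0.23). Of 24 interferon-stimulated genes, IRF7, ISG15 and IFIT2 were lower in all 3 EPCaTs, with ISG15 at 1224, 957, 1312 and 3309 CPM in the PF, 2% PEGDA, 3% PEGDA and 2D libraries (median -0.41). Of 14 immediate early genes, 4 were lower (median -0.70), among them MYC (3.56- to 3.91-fold), IER2 (2.56- to 3.20-fold) and IER3 (2.84- to 4.03-fold). Of 8 Notch genes, the ligand genes JAG1 (4.94- to 5.64-fold) and DLL4 (5.94- to 7.50-fold) were lower in all 3 (median -0.52). Wnt targets had a median of -0.53, with MYC and LEF1 lower and RNF43, which marks Wnt receptors for removal, 4.57- to 6.29-fold higher, with 71% of its 50-mers in other genes. The 15 TGF-beta targets had a median of -0.69, with 1 lower in all 3.

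PSCA, the prostate stem cell antigen gene, was 13.3- to 20.4-fold higher in the EPCaTs, the only call in all 3 among 10 stem cell associated genes (median 0.02). Of 5 measured neuroendocrine genes, ENO2 (6.33- to 7.19-fold) and SCG2 (5.84- to 10.4-fold) were higher and the synaptotagmin gene SYT1 2.48- to 3.71-fold lower (median 0.59). ENO2 is also a member of the glycolysis list. Among p53 targets (median -0.27), TP53INP1 and BTG2 were 2.89- to 4.02-fold and 2.51- to 4.23-fold higher, and AEN and PLK3 lower. Among antigen presentation genes (median 0.41), NLRC5, an activator of MHC class I genes, was 2.10- to 4.26-fold higher and PSMB9 2.04- to 2.76-fold. B2M was 2.20-fold higher with 3% PEGDA than in PF. Antioxidant NRF2 targets had a median of 0.10 against 2D, with AKR1C2 2.98- to 5.75-fold higher. Replication-dependent histones had a median of -0.01 and reference genes -0.00, with PGK1 the one reference gene past the rule against 2D. The table held none of the mitochondrially encoded genes.

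In PF+3%PEGDA, 19 of 26 G2 and M phase and 6 of 25 S phase genes were lower than in PF, and 7 and 1 were lower than in PF+2%PEGDA. With the length and GC trend removed, the G2 and M phase median in PF+3%PEGDA against PF was -1.33 (-1.73 to -1.18). In these libraries that trend does not account for the lower median. Fewer PC-3 cells would lower epithelial markers alike, but their median was -0.059 (-0.21 to 0.05). More nuclear RNA in the PF library would leave the PEGDA libraries level, yet PF+3%PEGDA against PF+2%PEGDA gave -0.92 (-0.98 to -0.79). That ratio leaves the PF library out, so it cannot tell how much of the difference from PF comes from nuclear RNA. Slower division with PEGDA may explain the lower cell division genes and stays a hypothesis, untested with 1 library per gel.

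Nuclear transcripts were higher and ribosomal protein genes lower in the PF EPCaT. A list of 16 genes known for retained introns or for retention in the nucleus was written before their values were seen. Their median in PF+3%PEGDA against PF was -0.90 (-1.49 to -0.65), with 7 lower and 0 higher. A larger share of nuclear, incompletely spliced RNA in the PF library may therefore be a candidate explanation; CCNL2 measured -2.26 and NKTR -1.59. In these libraries the length and GC trend does not account for these genes, at -0.95 (-1.57 to -0.57) once it was removed. Nor was it the whole cause for the ribosomal proteins, at 0.70 (0.51 to 0.96). Whether handling of the RNA or the gel made the difference stays open, since the PF gel has 1 library.

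Most fibroblast markers were lower in the EPCaTs than in 2D, and 9 of 22 collagens were lower in PF+3%PEGDA than in PF, against 3 in PF+2%PEGDA. A smaller share of BJ-5ta cells in the EPCaTs could lower CTNNA1, deleted in PC-3. Its mean log2 ratio was -2.34, with means of -2.67 and -2.03 for the lower and upper bounds of the 3 intervals. These means are not an interval of the mean ratio. With 1 gene, share and expression per cell cannot be told apart. In PF+3%PEGDA against PF, CTNNA1 stood at 0.62 (0.21 to 1.04), and the share between gels stays open for the same reason. With the length and GC trend removed, the collagen median was -0.46 (-1.21 to -0.15) in place of -0.71. Its interval over member genes reaches past the -0.2 that the trend would need. An effect of the gel on fibroblasts stays open and untested.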
